A study of Mus musculus with 8 samples.

How the data were processed

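Messenger RNA was measured by sequencing in the whole cortex of 8 mice, 4 labelled heterozygous for Mef2c and 4 labelled wild type, with 2 males and 2 females in each genotype. Per the labels' protocols, total RNA was extracted with a column kit, checked on a Bioanalyzer, enriched for polyadenylated RNA and sequenced after the samples had been randomised. RNA integrity numbers lay between 8.6 and 9, with means of 8.85 ± 0.173 (SD, n = 4) in the heterozygous group and 8.78 ± 0.150 (SD, n = 4) in the wild type group.

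The authors deposited raw read counts per gene symbol, and nothing in the values points to a normalisation by them. Per the submitters' processing notes, the tools were STAR 2.5.2b and HTSeq and the genome build was mm10. The gene annotation, the strand setting and any filter are not given in the sources used here. Without a stated strand setting, reads of a gene and of an antisense partner cannot be told apart, and reads of near-identical copies could be split between them. The table has 22000 rows, of which 4602 held no read in any library. The 13 rows of mitochondrially encoded genes held 0 reads, so that list was not tested. Of the rows, 19883 were matched by symbol or older symbol to GENCODE release 21 of the mouse genome build GRCm38, which gave identifiers and coordinates. Total counts per library lay between 16092773 and 17841377. The 10 most abundant genes took between 2.95% and 3.17% of the reads of a library.

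All steps from here on were computed from the deposited counts. Genes were kept with edgeR's filterByExpr by genotype at its minimum count of 10, which left 13879 genes and 99.95% of the reads, and libraries were scaled by TMM. Levels are given as CPM, the counts scaled to a common library total. The main test was edgeR's quasi-likelihood F-test (edgeR 4.0.16 in R 4.3.3, robust fit) with sex and genotype as terms, and a Benjamini-Hochberg adjusted p under 0.05 was called. The same fit gave the sex difference, and a fit with an interaction term gave the difference in the genotype effect between males and females. The Mef2c level was also tested with a two-sided exact permutation test over the 4 against 4 libraries, whose smallest possible p is 0.0286. The 8 libraries were separate mice per the labels. No pair of libraries within a genotype agreed within sampling noise, since the lowest chi-square per degree of freedom was 4.22.

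The 41 gene lists covered cortical cell types, neighbouring brain regions, immune, synaptic and metabolic pathways, described MEF2 targets, autism genes and RNA quality, and were fixed before the data were examined. Of these, 40 were tested with limma's camera (limma 3.58.1) on voom values at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were alternatives. A list's score is the mean over its tested members of log2 CPM, with a pseudocount of 0.5 CPM, after centring each member.

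Named genes were chosen by a rule fixed before the data were examined. It takes Mef2c and, among called genes with a mean log2 CPM of at least 1 and no overlap between the genotypes, the 12 largest rises and the 12 largest falls. It adds up to 4 called members of each list by smallest p, or up to 2 members where none was called. It also holds Xist, for which no value is given here, and the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y. Some other genes, such as Nrsn1, are named below outside this rule.

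The pipeline was tested on simulated counts for the same 13879 genes and the heterozygous against wild type comparison, with 50 genes changed at each size. It recovered 42% of genes changed 1.25-fold (21 of 50), 72% at 1.5-fold (36), 84% at 2-fold (42) and 96% at 3-fold (48). There were 16 false calls, a larger share of all simulated calls than the adjusted p threshold aims at. The 37 calls in the data may therefore hold more false ones than that threshold stands for. More genes were called in the simulation than in the data, so these recovery rates may be too high for the data. In the simulation of the gene lists without any change, 1 of 40 lists was called. Genes were drawn independently there, so it cannot show how camera behaves when the members of a list are correlated.

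The alternatives were size factors from DESeq2 (1.42.0), upper-quartile scaling, no filter and a stricter filter (1 CPM in 4 libraries), the DESeq2 Wald test, limma-voom, other covariates, 1 surrogate variable from sva (3.50.0), each sex alone, other thresholds, and each library left out in turn. The animal numbers in the sample titles run from 471 to 477 and from 498 to 502, with 1 animal of each sex and genotype in either run. They are called the first and the second series here, and the labels do not say what they stand for. Alternatives added after the data had been seen are named as such where their values stand. Intervals and floors cover counting error only.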

Results

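Gene expression was measured in the whole cortex of mice labelled heterozygous for Mef2c, a transcription factor gene of neurons and microglia, and of control mice labelled wild type. The question named by the series is how reduced MEF2C function in neuronal and neuroimmune cells relates to the behaviours of the human haploinsufficiency syndrome. Each genotype had 4 mice, 2 males and 2 females, with 1 library per mouse. Total counts were 16911381, 17316632, 16092773 and 17841377 in heterozygous replicates 1 to 4 and 17275407, 17263471, 17546866 and 16405265 in wild type replicates 1 to 4.

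Mef2c counts were higher, not lower, in the libraries labelled heterozygous. Mean levels were 1304 ± 73.2 CPM (SD, n = 4) in the libraries labelled heterozygous and 995 ± 41.3 CPM (SD, n = 4) in those labelled wild type, a 1.31-fold difference. The 4 libraries labelled heterozygous had 1233, 1336, 1391 and 1255 CPM, and the 4 labelled wild type had 1038, 939, 999 and 1003 CPM, so the groups did not overlap. The log2 fold change was 0.39 ± 0.05 (SE), with an adjusted p of 0.000154 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The two-sided exact permutation p was 0.0286, the smallest that 4 against 4 libraries allow. Within the first and second series of animal numbers the log2 fold change of Mef2c was 0.38 and 0.40. The gene (ENSMUSG00000005583.16, protein coding) lies on the plus strand of chromosome 13 from 83504034 to 83667080 in GRCm38. A count over the whole gene does not separate the alleles, and the labels do not say which part of the gene was altered. This direction goes against what the genotype label would give for a lost transcript, so every direction below refers to the libraries as labelled.

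**Figure D1:**
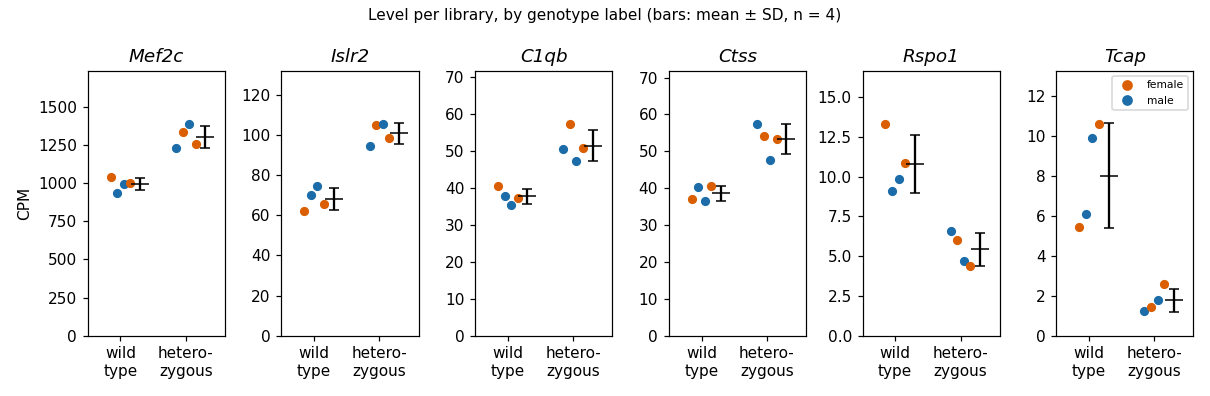
Level of 6 genes in each library in CPM, by genotype label, with females in orange and males in blue and bars for the mean ± SD (n = 4). Mef2c, Islr2, C1qb and Ctss lie higher in all 4 libraries labelled heterozygous, and Rspo1 and Tcap lie lower, with Tcap at 1.77 CPM against 8.01 CPM.

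The comparison of the genotypes asked which cortical transcripts differ with Mef2c genotype. In the libraries labelled heterozygous, the complement genes C1qb, C1qc and C4b and the lysosomal protease gene Ctss were higher. Tcap, Mylk3 and Tnnc1, which are known from striated muscle, were lower, as were Rspo1, which codes for a secreted enhancer of Wnt signalling, and Adcyap1, which codes for the neuropeptide PACAP. Of 13879 genes tested, 37 were called, 18 higher and 19 lower. Most changes were small: 13 of the higher and 10 of the lower genes changed by less than 1.5-fold, and 1 higher and 3 lower genes reached 2-fold.

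The largest rise was that of Figf, the gene of a vascular growth factor, from 1.39 to 3.35 CPM, a log2 fold change of 1.27 ± 0.27 (SE). Fibcd1 rose from 10.4 to 17.7 CPM (log2 fold change 0.77). A row named Drd, a symbol that matched no gene of the annotation used here, rose by 0.70. C4b, a complement component on chromosome 17 from 34728380 to 34743882, rose from 7.54 to 11.9 CPM (0.66 ± 0.13 SE), and its reads could be shared with a near-identical neighbouring copy. Ntn5, of the netrin family, rose by 0.62 and the protease gene Prss23 by 0.58. Islr2, a membrane protein gene of axon guidance on chromosome 9 from 58196297 to 58204319, had the smallest adjusted p of all genes, 0.000145 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, at 101 ± 5.34 against 68.3 ± 5.44 CPM (SD, n = 4). Ctss rose by 0.47 ± 0.07 (SE) and C1qb by 0.45 ± 0.07 (SE). Wfs1, an endoplasmic reticulum protein gene, rose by 0.44, and Stac2, whose product binds calcium channels, and the kinase gene Cdk18 each rose by 0.40. Further called rises were those of the AMPA receptor subunit gene Gria1 (0.22) and of Fkbp5 (0.45), a gene induced by glucocorticoids, which was the 1 called gene whose groups overlapped.

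The largest fall was that of Tcap, the gene of the sarcomere protein telethonin, on chromosome 11 from 98383811 to 98384953, from 8.01 ± 2.63 to 1.77 ± 0.585 CPM (SD, n = 4), a log2 fold change of -2.18 ± 0.27 (SE). Mylk3, a myosin light chain kinase gene of the heart, fell from 4.67 to 1.46 CPM (-1.68 ± 0.25 SE), and Tnnc1, the slow and cardiac troponin C gene, from 14.4 to 5.84 CPM (-1.30 ± 0.20 SE). Cmya5 and Igfn1, also known from muscle, fell by 0.81 and by 0.73 on the log2 scale. Rspo1, on chromosome 4 from 124986430 to 125009099, fell from 10.8 ± 1.84 to 5.42 ± 1.05 CPM (SD, n = 4). The kinase gene Plk5 had a log2 fold change of -0.93, Ramp3, whose product modifies peptide hormone receptors, -0.71, and the serotonin receptor gene Htr7 -0.64. Adcyap1 had -0.58, the cadherin gene Cdh6 -0.39 and Ankrd6 -0.38. Rasgrf2, a Ras exchange factor gene on chromosome 13 from 91880400 to 92131656, fell by 0.33 and Nrsn1 by 0.28 on the log2 scale.

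Of the 37 called genes, 36 had no overlap between the genotypes, which follows largely from their selection by the same libraries. By chance 2.86% of genes would have no overlap, and 4.55% of all tested genes had none. The count of calls depended on single libraries: it was 19 without wild type replicate 2, 23 without wild type replicate 1, 24 without heterozygous replicate 2 and 80 without heterozygous replicate 1, and 14 of the 37 genes, Mef2c, C1qb, Ctss and Tcap among them, were called with any library left out. Among the others, Figf kept its call in 2 of the 8 such fits, Fkbp5 in 4, and Gria1 and Ntn5 in 1 each. The count of calls was 72 with the series of animal numbers as a further term and 79 with the DESeq2 Wald test, and both kept all 37.

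**Figure D2:**
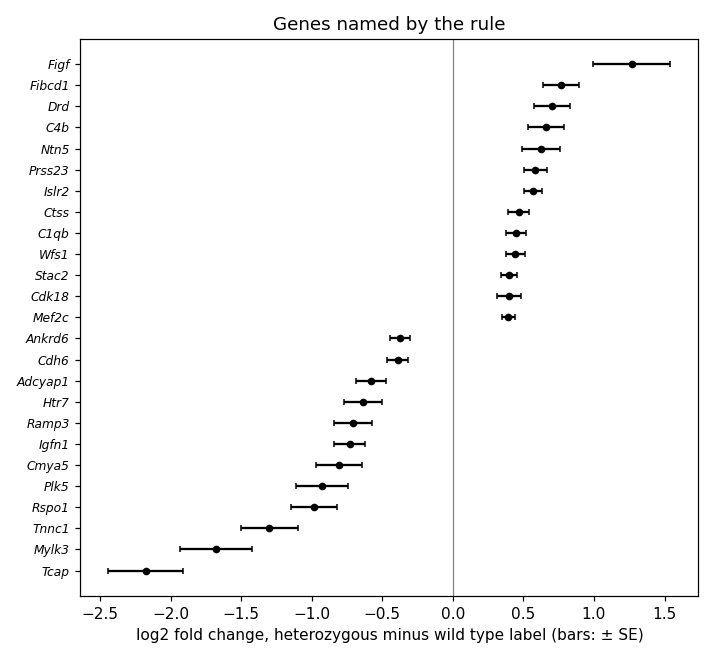
Log2 fold change (libraries labelled heterozygous minus wild type) of Mef2c and the 12 largest rises and 12 largest falls among called genes without overlap between the genotypes, with bars for ± SE. Values run from -2.18 for Tcap to 1.27 for Figf.

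The gene lists asked whether cell types or pathways moved together. Of the genes of homeostatic microglia, the resident immune cells of the brain, 3 of 30 tested members were called, Ctss, C1qb and C1qc, all higher, and 27 did not pass. C1qb and Ctss were called with any library left out, and C1qc was lost without heterozygous replicate 1, 2 or 4 or wild type replicate 1, 2 or 3, which left 2 called members. Of the 30, 22 had a log2 fold change above 0, and the median was 0.14. The score of heterozygous replicate 3 (-0.0679) lay inside the range of the libraries labelled wild type (-0.0927 to 0.0082), and the two-sided exact permutation p of the scores was 0.0857. Adjusted over the list alone, 9 were higher and 1, the sugar transporter gene Slc2a5, was lower. The list of complement and Fc receptors had 3 of 20 tested members called, C1qb, C4b and C1qc, all higher, with a median of 0.16, and 6 were higher adjusted over the list alone. C4b was lost without heterozygous replicate 2 or 3 or wild type replicate 1, 2 or 3, and C1qb was the 1 called member without heterozygous replicate 2 or wild type replicate 1, 2 or 3. The microglia list had an adjusted p of 6.44e-06 and the complement list one of 9.88e-05 in camera with the preset correlation and Benjamini-Hochberg adjustment. With an estimated correlation, camera gave an adjusted p of 0.726 for the microglia list and 0.283 for the complement list. The 2 lists shared 6 tested members, and without these, an alternative chosen after the data had been seen, the homeostatic microglia list had an adjusted p of 0.00665 in camera and the complement and Fc receptors list one of 0.121.

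Of the markers of red blood cells, all 5 tested had a log2 fold change below 0, with a median of -0.40, no member was called, and 2 were lower adjusted over the list alone. Heterozygous replicate 4 had the lowest score of the list (-0.972), and the score difference between the genotypes was -0.55 with it and -0.32 without it. Hbb-bt had 1.98 CPM against 3.86 CPM and Alas2 1.64 CPM against 2.92 CPM. The adjusted p of this list was 3.84e-05 in camera with the preset correlation and 0.726 with an estimated correlation. Markers of activated microglia had a median of -0.001 with no member called, and those of perivascular macrophages and blood leukocytes one of 0.27 over 5 members, also with none called.

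**Figure D3:**
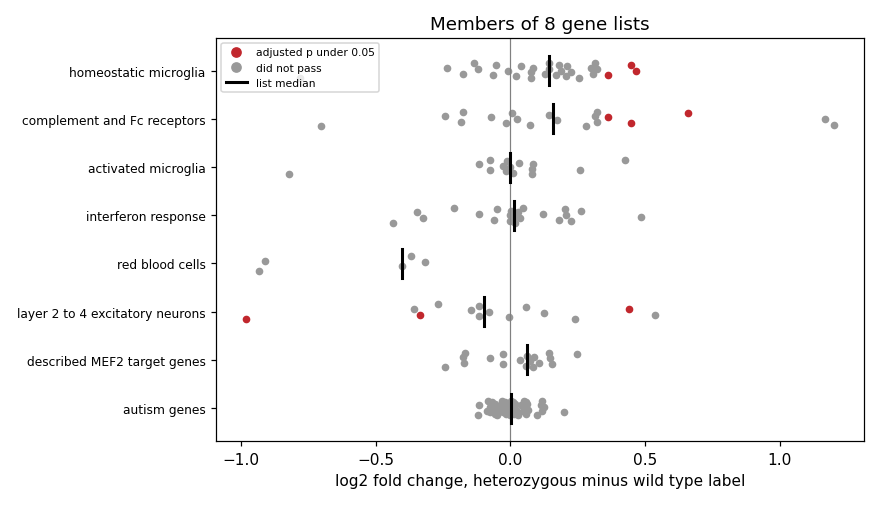
Log2 fold change (libraries labelled heterozygous minus wild type) of each tested member of 8 gene lists, with called genes in red, other genes in grey and the list median as a black bar. The medians of the microglia and complement lists are 0.14 and 0.16, and that of the red blood cell list is -0.40.

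In all, camera with the preset correlation called 6 of 40 lists, 5 higher and 1 lower, while camera with an estimated correlation called 0 (2 at an unadjusted p under 0.05) and fry called 0 for a common direction (2 at an unadjusted p under 0.05). Fry without regard to direction called 8 lists (11 at an unadjusted p under 0.05), those of homeostatic microglia, complement, excitatory neurons, layer 2 to 4 excitatory neurons, thalamus, axon guidance, the MEF2 family and genes near Mef2c. Other divisions of the same 8 libraries into 4 and 4 gave up to 11 called lists in camera with the preset correlation. Fry was not run on those divisions. The other called lists were those of striatum markers (median 0.21), the circadian clock (0.06) and ribosomal proteins (0.02), with no member of them called. Their adjusted p in camera was 0.0113, 0.0411 and 0.0466 with the preset correlation and 0.923, 0.923 and 0.992 with an estimated correlation. The median of the striatum list was 0.46 in the first series of animal numbers and -0.16 in the second, and the call ended without heterozygous replicate 1 (adjusted p in camera 0.325), heterozygous replicate 2 (0.365), wild type replicate 1 (0.265) or wild type replicate 3 (0.0699). The call of the circadian clock list ended without heterozygous replicate 1 (0.0754), 3 (0.0936) or 4 (0.176) or wild type replicate 2 (0.382), and that of the ribosomal proteins list without heterozygous replicate 2 (0.538), 3 (0.101) or 4 (0.102) or wild type replicate 1 (0.886) or 3 (0.0901).

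Neuronal lists held single called genes in both directions. Of the 14 markers of layer 2 to 4 excitatory neurons, Wfs1 was higher and Rspo1 and Rasgrf2 were lower, with an adjusted p of 0.0941 for the list in camera. Rasgrf2 was also the 1 called gene among 22 excitatory neuron markers, Gria1 the 1 among 43 genes of glutamate receptors and the postsynaptic density, Adcyap1 the 1 among 22 neuropeptide genes, Ramp3 the 1 among 12 thalamus markers and Fkbp5 the 1 among 15 glucocorticoid response genes. Camera called none of these lists, while fry without regard to direction called those of excitatory neurons, layer 2 to 4 excitatory neurons and thalamus.

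The other lists had no called member and no call by camera. Among cell types, the medians were 0.06 for layer 5 and 6 excitatory neurons, 0.01 for inhibitory interneurons, -0.03 for astrocytes, 0.00 for mature oligodendrocytes, 0.00 for endothelial cells, -0.05 for pericytes and 0.12 for leptomeningeal fibroblasts; oligodendrocyte precursors, at -0.003, likewise lay near 0. Choroid plexus markers had a median of 0.20 over 5 members and hippocampus markers one of 0.15. The hippocampus marker Npnt, at 34.5 CPM against 56.0 CPM, had an adjusted p of 0.0692 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment and did not pass. Described MEF2 target genes had a median of 0.06, with 11 of 18 above 0, and autism genes one of 0.002 over 50 members. The median was 0.04 for activity-regulated genes, 0.02 for the interferon response, 0.01 for antigen presentation, -0.02 for GABA receptors, -0.01 for synaptic vesicle genes and -0.0004 for voltage-gated ion channels. It was 0.06 for extracellular matrix genes, -0.01 for axon guidance genes, 0.01 for oxidative phosphorylation, -0.01 for cholesterol synthesis and -0.01 for the heat shock response. The MEF2 family and class IIa histone deacetylases, without Mef2c, had a median of -0.05, and genes near Mef2c one of 0.03. The median, mean and camera direction differed in sign for 9 uncalled lists, those of activated microglia, mature oligodendrocytes, oligodendrocyte precursors, endothelial cells, pericytes, thalamus, antigen presentation, activity-regulated genes and genes near Mef2c.

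The comparison of the sexes checked the sex labels. Males had lower levels of the X-linked genes Ddx3x and Eif2s3x, which escape X inactivation (male minus female log2 fold changes of -0.37 and -0.52), and higher levels of the Y-linked genes Kdm5d and Ddx3y. These 4 genes were the ones called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 405 genes had an unadjusted p under 0.05. The Y-linked genes Uty and Eif2s3y did not pass, with adjusted p of 0.0702 and 0.162 in the same test. Their male minus female log2 fold changes were 6.32 and 6.84, so the fit missed large known differences. The 4 male libraries held 2564, 2150, 2391 and 2389 reads of Ddx3y, Uty, Kdm5d and Eif2s3y together, and 3 of the female libraries held 0, 3 and 0. Heterozygous replicate 4, labelled female, held 72 such reads, 2.88% of the male mean (95% exact Poisson interval 2.26 to 3.63). The count of calls was 2 without wild type replicate 3.

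The interaction of genotype and sex asked whether males and females differed in the genotype effect. No gene was called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with 366 genes at an unadjusted p under 0.05 and 2 mice per sex and genotype. In the fit of all 8 libraries, Mef2c had a log2 fold change of 0.34 in females and 0.44 in males.

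Around Mef2c on chromosome 13, the called genes Rasgrf2 and Cmya5 (93040713 to 93144724) had, in the first and second series of animal numbers, log2 fold changes of -0.37 and -0.30 for Rasgrf2 and of -0.85 and -0.77 for Cmya5. Rasgrf2 was called with any library left out, and Cmya5 was lost without heterozygous replicate 2, 3 or 4 or wild type replicate 1, 2 or 4. The neighbouring gene Tmem161b (84222296 to 84296141) had -0.45 and -0.27 and did not pass. Tmem167 (90089123 to 90143907), singled out after its values were seen, had 0.01 in the first series and -1.04 in the second.

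**Figure D4:**
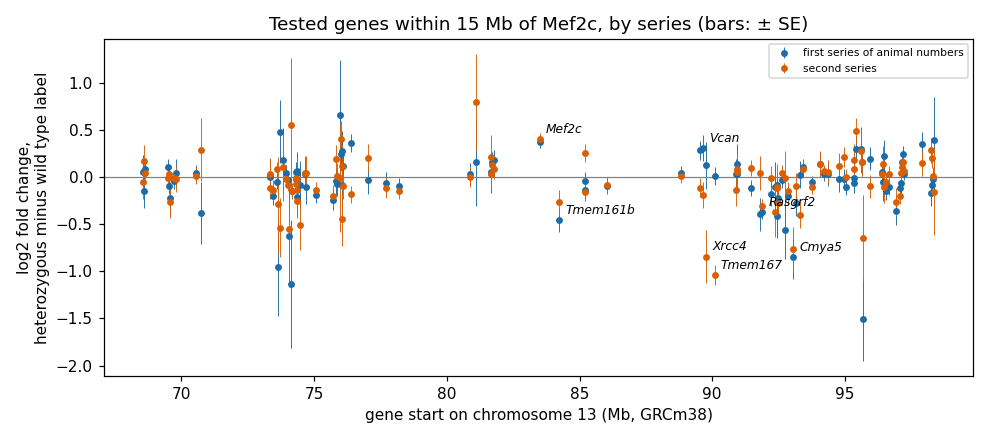
Log2 fold change (libraries labelled heterozygous minus wild type) of tested genes within 15 Mb of Mef2c on chromosome 13, by gene start in Mb, in the first series (blue) and second series (orange) of animal numbers, with bars for ± SE. Mef2c lies at 0.38 and 0.40, and Tmem167 lies at 0.01 in the first series and -1.04 in the second.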

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

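Apart from the counts over all splits, all tests below were chosen after the result they bear on was seen, and what each test, the splits included, would show was written down only after it had been run. They can therefore argue against an explanation but give no independent support for one. Of the 35 splits of the 8 libraries into 4 and 4, 34 could be fitted with the other factor (sex, or genotype for the sexes) as a term. For the genotype comparison 1 of the 34, the real one, gave as many as 37 genes, and the highest other split gave 23. That highest split was the one that follows the series of animal numbers, and with the series as a term the genotype count was 72. The 34 splits are therefore not alike, and their share alone does not exclude chance for the count of 37. Only 18 of the splits put 2 libraries of each series into either group. Of these, 17 could be fitted with sex and series as terms, too few for a share under 0.05: 1 of the 17, the real one, gave as many as 72 genes, and the highest other gave 4. For the gene lists 24 of the 34 splits gave 6 or more, with up to 11, so chance cannot be excluded for the number of lists. For the sexes 6 of the 34 splits gave 4 or more genes, and the highest, which follows the series, gave 51. This points to a structure of the samples along the series.

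The first pattern is that Mef2c counts were higher in the libraries labelled heterozygous. Scaling of the libraries is argued against. The smallest log2 fold change over DESeq2 size factors, upper-quartile scaling, the DESeq2 Wald test and the raw counts was 0.38. Reads of the other MEF2 genes counted on Mef2c are argued against too, since the summed level of Mef2a, Mef2b and Mef2d did not fall but changed by 12.2% of the rise of Mef2c. An exchange of the 2 genotype labels as a whole cannot be told apart from correct labels here, because the described MEF2 target genes went both ways (adjusted p 0.843 in camera). A biological response of the remaining or altered allele stays open and untested.

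The second pattern is that called microglia and complement genes were higher in the libraries labelled heterozygous, C1qb and Ctss with any library left out and C1qc and C4b in 2 and 3 of the 8 fits with 1 left out. The calls of the lists themselves are lost with an estimated correlation (adjusted p 0.726 and 0.283 in camera). More blood left in the tissue is argued against by the median of -0.40 over the 5 red blood cell genes. Their score difference was -0.55 ± 0.29 (SE), and -0.32 ± 0.19 without heterozygous replicate 4. Both lay more than 2 SE below the microglia median of 0.14 (this rule replaced a first one, that all 5 lie below 0, with the same outcome). The red blood cell genes do not cover perivascular macrophages and blood leukocytes, whose markers had a median of 0.27 over 5 members, none called. An equal rise of all microglial transcripts, which a larger number of unchanged microglia could give, stays open. The spread of the 30 members around their common shift was larger than in any other of the 35 splits (permutation p = 0.0286, the smallest they allow). The permutation alone does not decide. Its members were weighted by their SE in the fit of the real genotypes, which can favour the real split. The 18 splits with 2 libraries of each series are too few for a p under 0.05. The permutation test had replaced the large-sample one. Chance stays open for the number of lists, as 24 of 34 splits gave as many, and a change of gene use within microglia is a hypothesis left open.

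The third pattern is that 53 genes differed between the 2 series of animal numbers, 24 higher and 29 lower in the second (edgeR quasi-likelihood test with sex, series and genotype as terms). Of the 51 with a known position, 8 lay within 10 Mb on chromosome 17, Amdhd2 and Unkl among them, where the highest of 10000 random sets had 7 (permutation p = 0.0001, the smallest they can give), so an inherited difference in a linked stretch of chromosome is a candidate explanation for that part. A lower share of blood vessel cells could account for the 22 endothelial genes, all below 0 with a median of -0.40 (adjusted p 0.357 in camera with an estimated correlation), but not for the whole, as 24 genes were higher in the second series. A difference in handling or age between the series stays open and untested, since the labels do not say what the numbers stand for.

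Among 266 groups of 4 libraries, covering named genes, list scores and library totals, 13 held a library far from the other 3, where chance gives about 1 in 20, or 13.3. Igfn1 was at 21.2 CPM in heterozygous replicate 3 against 14.4 to 15.2 CPM in the others, and at 28.9 CPM in wild type replicate 4 against 26.5 to 26.8 CPM. Dusp4 was at 9.32 CPM in heterozygous replicate 3 and Tsc1 at 77.2 CPM in heterozygous replicate 2. In heterozygous replicate 3 the homeostatic microglia score was -0.0679 (0.0801 to 0.109 in the other 3), the excitatory neuron score 0.0003 and the described MEF2 target score -0.0379. In heterozygous replicate 1 the inhibitory interneuron score was -0.0414, the leptomeningeal fibroblast score -0.424 and the voltage-gated ion channel score 0.0627. The activity-regulated gene score was -0.177 in heterozygous replicate 2 and 0.133 in wild type replicate 1, and the antigen presentation score -0.147 in wild type replicate 3.

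The genotypes differed in library total in opposite directions in the sexes, by -1.64 when totals are counted in units of 1e6 reads (male minus female effect), and this difference was not tested; of 133 results checked, it was the 1 in which the genotypes did not overlap in either sex and lay in opposite order in the 2 sexes, where chance gives 5.56%. The genotype effect on Tmem167 differed between the series by -1.05 on the log2 scale, the 1 gene called for that interaction by edgeR's quasi-likelihood test (adjusted p 0.00217). Heterozygous replicate 4, labelled female, held 72 reads of 4 Y-linked genes, where the other female libraries held 0 to 3.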

How the results depend on the processing

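Mef2c kept its call under all alternatives run, with log2 fold changes from 0.35 (females fitted alone) to 0.44 (males fitted alone). The count of 37 genes was 82 without a filter on low counts, 79 with the DESeq2 Wald test, 72 with the series of animal numbers as a term, 90 with 1 surrogate variable, 72 at an adjusted p of 0.1, 7 in males only, 6 in females only and, in an alternative chosen after seeing the data, 97 with sex, series and RIN. With single libraries left out it ran from 19 to 80. All 37 genes were kept with DESeq2, limma-voom, the series and the surrogate variable. The 6 called lists became 0 with an estimated correlation, 0 with fry for a common direction, 10 in females only and 3 without the members shared by the microglia and complement lists, a choice made after seeing the data; with single libraries left out they ran from 4 to 8. The sex count of 4 ran from 2 to 6 and the interaction count of 0 from 0 to 2 with single libraries left out. Each sex alone leaves 2 against 2 mice, and the cause of these shifts was not tested. On a scale of signed -log10 p from camera, the mature oligodendrocytes and myelin list went from -0.07 to 2.82 without heterozygous replicate 2 and to -2.67 without heterozygous replicate 4, the range over left-out libraries, and the ribosomal proteins list from 2.16 to -0.38 in males only; the cause was not tested. The scalings moved the median of all genes by at most 0.00248. At totals of 16092773 to 17841377 reads, 3 reads correspond to at most 0.186 CPM.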

Other observations

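The following tests were chosen after their results had been seen, and the tests of Tmem167, of the genes near Mef2c and of the muscle genes were revised after they had been run: the first form for Tmem167 included the gene itself, the second used the genotype by series term, the first form for the genes near Mef2c used all 8 libraries alone, and the first form for muscle used the preset correlation alone. Between the 2 series of animal numbers, the neuronal GABA receptor gene Gabra2 on chromosome 5 had the smallest adjusted p. In a fit with sex and genotype as further terms, its log2 fold change was -0.82 ± 0.07 (SE, second minus first). The adjusted p was 1.39e-07 in edgeR's quasi-likelihood test. Mean levels of Gabra2 were 72.4 ± 3.39 CPM (SD) in the second series and 129 ± 24.2 CPM (SD) in the first. Of 22 endothelial markers 6 were called, all lower in the second series, among them Vwf (-0.69) and Pecam1 (-0.53), and the list had an adjusted p of 3.82e-21 in camera with the preset correlation and 0.357 with an estimated correlation. Markers of leptomeningeal fibroblasts and of myelin lay mostly higher in the second series. None of 18 fibroblast markers (median 0.30) and 2 of 23 myelin markers (median 0.16) lay below 0, and 1 and 2 of them were called, all higher. The 2 lists had adjusted p of 8.06e-07 and 1.37e-09 in camera with the preset correlation and 0.517 for both with an estimated correlation.

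Tmem167 on chromosome 13 was lower in the 2 second-series libraries labelled heterozygous, at 25.6 CPM on average against 53.4 ± 2.71 CPM (SD, n = 6) in the other 6. Its annotated start (90089123) lies within Xrcc4 (89774027 to 90089608, on the other strand), so the reads of the 2 genes are not fully separate. A candidate explanation is a stretch of chromosome 13 that differs in those 2 animals. In those 2 libraries against the other 6, Xrcc4 had a log2 fold change of -1.10 and Vcan one of -0.28, while Atg10 had 0.34. The 6 tested neighbours within 1 Mb together did not stand apart from the neighbours of other genes with as many (a share of 0.0949 of them moved as far), so the test does not decide. The share was 0.00422 for the genotype by series term, which also holds the higher first-series values of Hapln1 (0.29) and Vcan (0.31).

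Apart from Mef2c, 2 of 63 tested genes within 10 Mb of it were called, Rasgrf2 and Cmya5, against 33 of 13339 elsewhere (two-sided Fisher's exact p = 0.0117). With 1 library left out, p was under 0.05 in 2 of 8 fits, without heterozygous replicate 2 (0.00526, with Homer1 in place of Cmya5) and without wild type replicate 3 (0.0116). It was 0.0529 without heterozygous replicate 1, and 1 gene was left, Rasgrf2, without heterozygous replicate 3 (0.141) or 4 (0.116) or wild type replicate 1 (0.0979), 2 (0.082) or 4 (0.131). Whether a change carried on the chromosome 13 stretch around Mef2c accounts for these genes therefore stays open. Tmem161b, next to Mef2c, had 19.5 CPM in the libraries labelled heterozygous against 24.98 CPM in the others and did not pass.

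The 5 muscle genes among the called falls led to the hypothesis that sarcomere genes fall as a class. Of 37 other sarcomere and striated muscle genes tested, 0 were called and 26 lay below 0, with a median of -0.20. Camera gave p = 0.00859 with the preset correlation and p = 0.137 with an estimated correlation, so the test does not decide, and the preset form was seen to call lists in many other splits of these samples.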
